A study of Mus musculus with 4 samples.

How the data were processed

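The data came from mammary epithelial cells of 4 week-old mice on an FVB/NJ background, 2 samples from mice carrying an MMTV-Cre transgene and 2 from wild-type littermates, with 1 Affymetrix array per sample. Per the labels, cells were obtained from inguinal glands described as free of lymph node, by mincing, collagenase digestion and centrifugation to remove stroma. The labelled cDNA was made from 50 ng of total RNA with a kit for small amounts of input. The deposited values are log2 expression per probe set, made by the authors with the oligo package and the RMA method, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises probes into probe sets. The log2 scale was taken from the values themselves, which were all positive and had array medians between 2.83 and 2.86. Versions of oligo and RMA and the annotation behind the probe sets are not given in the sources used here. Because RMA equalises the arrays, a shift shared by most transcripts cannot be seen in these values.

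Each array held 41345 probe sets. Gene names came from the platform annotation, in which 23521 probe sets had 1 gene symbol, 1814 had several and 16010 had no gene named here. Only probe sets with 1 symbol entered the gene comparison, and a gene with several was represented by the one with the highest mean over the 4 arrays. Of 22180 genes, the 11668 whose mean lay at or above 2.84, the median over all probe sets, were tested. Among them 807 had more than 1 probe set, and 11602 were matched by Entrez identifier to the RefSeq gene table of mouse assembly GRCm38.p6, which was used for gene class and gene order only.

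Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without a trend, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Intervals are 95% intervals from that fit. A set of 37 gene lists for mammary cell types, pathways, sample quality and other cell types was fixed before the data were examined, and so were the tests, the alternatives and 28 genes of lineage, hormone response, proliferation, p53 response and other cell types. Of these 28, Krt5 was left out because its probe set also carries Krt6a, Wap lay below the filter on dim probe sets, and Prlr, Areg and Trp53 were not analysed here. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry were alternatives. A list's level in an array is the mean over its members after subtracting each gene's mean over the 4 arrays. The standard error given for a list is over its members and does not measure variation between mice.

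The genes named in the text follow a rule set beforehand. It took the 12 genes with the largest difference in each direction among those past the threshold with separate groups, meaning that both arrays of a group lay on the same side of both arrays of the other. Open places went to genes that did not pass, by smallest unadjusted p among those with separate groups and means at least 1.5-fold apart. It also took up to 4 members of each described list by smallest p, and the 28 fixed genes. Predicted genes, small RNAs and pseudogenes were counted and not named. Genes named outside the rule are said to have been chosen after their values were seen.

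The alternatives were no filter and a stricter filter on dim probe sets, the mean of a gene's probe sets, each probe set tested separately, quantile normalization, median centring, a variance trend, robust variance, the replicate number as a block, other thresholds, other list tests, and leaving out each array in turn. The procedure was tested on 20 simulated data sets of 11668 genes with the arrays' means and spread. Of simulated changes in the comparison of MMTV-Cre with wild-type, 52.2% were recovered at a log2 difference of 1, 94.3% at 2, 98.7% at 3 and 99.2% at 4, and 0.0746% of unchanged genes were called. All sizes were planted together, 1000 genes of each over the 20 data sets, and the large changes ease the adjusted threshold for the small ones. Recovery would be lower in data with few changed genes. Lists of 20 genes that varied independently and were shifted by 0.3 log2 were called in 20 of 20 simulations, against 0 of 600 lists that were not shifted. Those simulations hold no correlation between genes. The number of arrays limits the precision of every comparison, and 2 samples against 2 cannot give a two-sided exact permutation p under 0.333.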

Results

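Transcript levels were measured on arrays in mammary epithelial cells from 4 week-old FVB/NJ mice. In 2 samples the mice carried MMTV-Cre, a transgene in which the long terminal repeat of mouse mammary tumour virus drives the Cre recombinase, and 2 samples came from wild-type littermates. The labels call the samples of a group biological replicates. Over the 11668 genes tested, the 2 MMTV-Cre arrays correlated at 0.983 and the 2 wild-type arrays at 0.980. Wild-type replicate 2 correlated at 0.986 and 0.987 with the MMTV-Cre arrays, above its correlation with wild-type replicate 1. These correlations are across genes, which are not independent replicates, and no 2 arrays were duplicates.

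The comparison asks how cells from Cre-expressing glands differ in their transcripts from those of wild-type littermates. No gene passed the limma threshold, and the hormone receptors, luminal and basal keratins, milk protein and cell-cycle genes chosen beforehand had differences whose intervals included 0. By camera with a preset correlation, the immediate early and dissociation stress list, fixed as a sample quality list, rose in MMTV-Cre. Its mean log2 difference was 0.18 (SE over 30 members 0.02, n = 2 per group). Handling of the tissue stays open as an explanation of that rise, and so does a p53 response. By the same test a small list of mast cell and neutrophil genes fell by 0.52 (SE over 6 members 0.13). Neither call held by camera with an estimated correlation (adjusted p = 0.955 for both) or by fry (adjusted p = 0.642 for both). With an estimated correlation 0 of the 34 lists reached an unadjusted p under 0.05. The power of that test with 4 arrays was not simulated. Transcripts of lymphocytes were high in wild-type replicate 1 alone. The calls of 4 of the 6 lists that passed did not hold without that array. The mean differences of the T and NK cell and interferon-stimulated lists then went from −0.88 and 0.16 to 0.01 and −0.00. Those of the fibroblast and p53 target lists changed little, from 0.13 and 0.09 to 0.12 and 0.09. The fibroblast and p53 target calls also ended without certain other arrays.

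Genes of the luminal hormone-sensing cells, which carry the oestrogen and progesterone receptors, had differences on both sides of 0, and none passed. The log2 difference, MMTV-Cre minus wild-type, was 0.11 for Esr1 (95% interval −0.19 to 0.41), 0.05 for Gata3 (−0.24 to 0.35) and 0.15 for Foxa1 (−0.32 to 0.62). The signalling gene Wnt4, the member with the smallest p, differed by −0.39 (−0.84 to 0.06) and was lower in both MMTV-Cre arrays, and Fgl2 differed by 0.25. The progesterone receptor Pgr averaged 5.95 in both groups, with an interval of −0.33 to 0.32. Among luminal progenitor genes, 10 of 16 had differences below 0. The carbonic anhydrase gene Car2 differed by −0.39 (−0.69 to −0.10) and was lower in both MMTV-Cre arrays, Slc34a2 differed by −0.34, Itga2 by −0.30 and Tnfrsf11a by −0.36, while the transcription factor Elf5 differed by 0.11 and the receptor Kit by 0.13. The luminal keratin Krt8 differed by −0.06 (−0.33 to 0.22), Krt18 by 0.18 (−0.09 to 0.45) and the epithelial adhesion molecule Epcam by −0.03 (−0.33 to 0.27). The basal genes Krt14 and Trp63 differed by −0.33 (−1.03 to 0.37) and −0.24 (−0.74 to 0.25), and by 0.08 and 0.01 without MMTV-Cre replicate 1. The milk protein gene Csn2 differed by 0.02 with a wide interval, −1.23 to 1.27. The proliferation gene Mki67 differed by 0.03 (−0.40 to 0.45) and Ccnd1 by −0.06 (−0.44 to 0.32). Erbb2, which encodes a receptor tyrosine kinase, differed by 0.27 (−0.13 to 0.67), and Stat5a, a transducer of prolactin signals, by −0.10 (−0.48 to 0.29). In all, 23 of the 28 genes chosen beforehand were tested, and 0 of them reached an unadjusted p under 0.05.

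**Figure D1:**
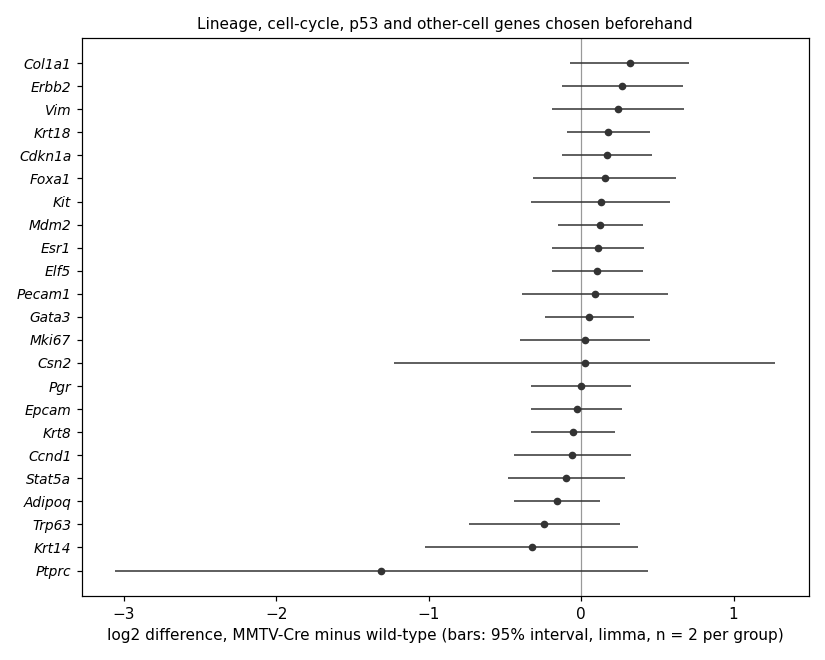
Each point is the log2 difference, MMTV-Cre minus wild-type, of 1 of the 23 tested genes chosen beforehand, and each bar is its 95% interval from limma with n = 2 per group. All bars cross 0, and the bar of Ptprc, a pan-leukocyte gene, runs from −3.06 to 0.44.

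Lists of these lineages did not pass the test with all 4 arrays. The mean log2 difference was 0.06 for the luminal hormone-sensing list (adjusted p = 0.329), −0.08 for luminal progenitors (0.389), 0.08 for basal and myoepithelial genes (0.161) and 0.07 for general epithelial genes (0.208). The oestrogen and progesterone response list had a mean of −0.05, the list for ductal outgrowth and branching 0.04, S phase −0.04 and G2/M phase 0.02. Without MMTV-Cre replicate 1 the basal list (mean 0.17, adjusted p = 0.0236) and the ductal list (mean 0.16, 0.0204) passed upward, and without MMTV-Cre replicate 2 their means were 0.00 (0.790) and −0.08 (0.523). The prolactin and STAT5 list had a mean of 0.01, a median of −0.05 and an upward test. The milk protein list had a mean of −0.21 but a median of 0.02 and an upward test, since Glycam1 stood at 10.19 in wild-type replicate 1 and at 2.72 to 2.87 in the other arrays. In all, 6 of 34 lists passed camera with the preset correlation, 28 did not, and 3 more had too few measured members. With an estimated correlation 0 lists passed (adjusted p = 0.955 for each of the 6), and by fry 0 passed (smallest adjusted p = 0.599). Correlation is not the only reason. The p53 target list had an estimated correlation of −0.04, below the preset 0.01, and its unadjusted camera p still went from 0.00779 to 0.0996. The T and NK cell list had an estimate of 0.81, far above the preset value. Estimates also lay above it for immediate early genes (0.11) and for neutrophils and mast cells (0.12). They were 0.47 for interferon-stimulated genes and 0.55 for fibroblast genes. If these estimates hold, the preset value makes the camera p-values of those lists too small.

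The immediate early and dissociation stress list rose in MMTV-Cre by camera with the preset correlation (adjusted p = 8.97e-06) and did not pass with an estimated correlation (adjusted p = 0.955, unadjusted p = 0.104). Of its 30 measured members, 27 had a difference above 0, 17 were higher in both MMTV-Cre arrays than in both wild-type arrays and 0 passed alone, also adjusted over the list alone. The list's mean stood 0.14 and 0.04 above its average over the arrays in the MMTV-Cre samples and at −0.09 in each wild-type sample, so it did not follow the lymphocyte transcripts of wild-type replicate 1. The transcription factor genes Egr1 and Jun differed by 0.44 (0.05 to 0.84) and 0.48 (−0.04 to 0.99). The chaperone genes Hsph1 and Hspa1a differed by 0.45 (−0.00 to 0.90) and 0.31 (−0.02 to 0.64). The differences of Jun and Hsph1 rested in part on wild-type replicate 1. Jun stood at 6.65 there and at 7.19 in wild-type replicate 2, against 7.37 and 7.42 in MMTV-Cre. Hsph1 stood at 5.82 and 6.15, against 6.58 and 6.28. The call held without any 1 array, with adjusted p from 6.18e-06 without MMTV-Cre replicate 2 to 0.0127 without MMTV-Cre replicate 1, and it was 1.80e-05 without wild-type replicate 1.

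The p53 target list rose by a mean of 0.09 (SE over 22 members 0.03, camera adjusted p = 0.0441), with an unadjusted p = 0.0996 under an estimated correlation. Of its members 16 had a difference above 0, 9 were higher in both MMTV-Cre arrays and 0 passed alone, also adjusted over the list alone. Psrc1 differed by 0.36 (0.04 to 0.68), Eda2r, a receptor of the tumour necrosis factor family, by 0.35, the cell-cycle inhibitor Cdkn1a by 0.17 (−0.13 to 0.46) and the p53 regulator Mdm2 by 0.13 (−0.16 to 0.41). The call ended without MMTV-Cre replicate 1 (mean 0.08, adjusted p = 0.298), without wild-type replicate 1 (mean 0.09, 0.107), without wild-type replicate 2 (mean 0.10, 0.298), and with no filter or a stricter filter on dim probe sets (0.114 and 0.137).

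The neutrophil and mast cell list fell in MMTV-Cre (camera adjusted p = 0.000182, unadjusted p = 0.0696 with an estimated correlation). Its 6 measured members all had differences below 0, and 4 were lower in both MMTV-Cre arrays than in both wild-type arrays. No member passed over all genes, and 2 passed adjusted over the list alone, the mast cell protease genes Mcpt4 (adjusted p = 0.0157 within the list) and Cma1 (0.0273). Mcpt4 stood at 2.69 and 3.06 in MMTV-Cre and at 3.77 and 3.73 in wild-type, a log2 difference of −0.87 (−1.28 to −0.47). Cma1 differed by −0.46 (−0.74 to −0.17) and Cpa3, a mast cell carboxypeptidase gene, by −0.73 (−1.32 to −0.14). The neutrophil gene Cxcr2 differed by −0.22. Mcpt4, Cma1 and Cxcr2 lay near the dim end of the arrays, where the size of a difference is uncertain. Cma1 stood at 3.04 and 3.11 in MMTV-Cre and at 3.49 and 3.58 in wild-type. Cxcr2 lay between 2.73 and 3.06 over all arrays. With no filter on dim probe sets the list held 16 members and passed downward (camera adjusted p = 0.00531). Under the stricter filter it had too few members to be tested. S100a9, chosen after its values were seen, was high in wild-type replicate 1 alone, at 5.19 against 3.60 to 3.82. Without wild-type replicate 1 the list's mean difference was −0.36 (adjusted p = 0.0332), the highest adjusted p among the fits without 1 array.

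Wild-type replicate 1 held 63 genes at least 1 log2 unit above all 3 other arrays, against 1, 2 and 1 such genes in the others. Of the genes named in this paragraph, Cd3g, Cd3d, Cxcl13, Cd2, Lat, Ighg3 and Satb1 were chosen after their values were seen. Glycam1, which encodes a ligand of L-selectin, stood at 10.19 there and at 2.72 to 2.87 in the others, about the 2.84 of a median probe set. The T cell receptor complex genes Cd3g and Cd3d stood at 6.63 and 6.17 in wild-type replicate 1 and at 2.71 or less in the others. The interleukin-7 receptor gene Il7r reached 6.41 against at most 3.54, and the B cell chemoattractant gene Cxcl13 reached 6.19 against at most 3.60. The immunoglobulin gene Ighm reached 7.36 against at most 3.80, although its 7 probe sets did not agree in size or sign. The brightest had log2 differences of −1.90, −0.87 and −0.66. The others, with means of 2.21 or less, lay between −0.13 and 0.23. Ptprc reached 6.96 against at most 4.82. When wild-type replicate 2 was left out, 13 genes passed the limma threshold, all highest in wild-type replicate 1, among them Glycam1, Cd3g, Cd3d, Cd3e, Cd2, Lat, Ptprc, Ighm, Ighg3 and Satb1.

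**Figure D2:**
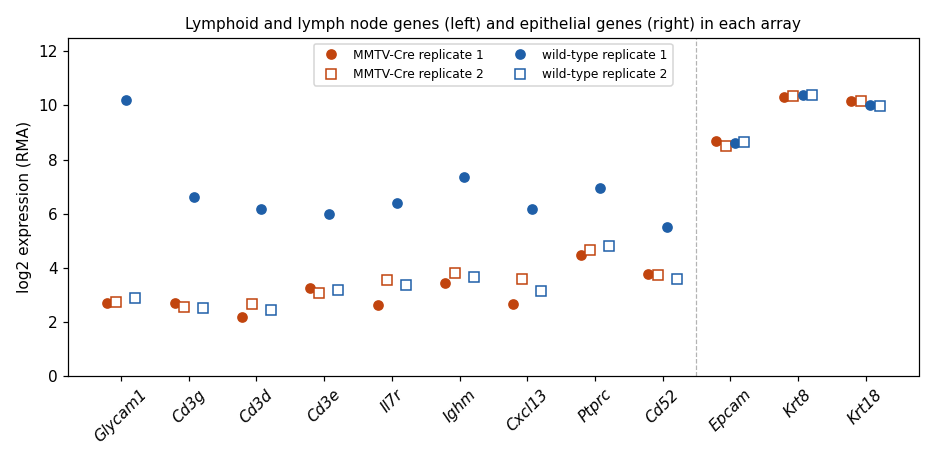
The log2 expression of lymphoid and lymph node genes (left of the dashed line) and epithelial genes (right) is plotted for each of the 4 arrays, 1 point per array. In wild-type replicate 1 Glycam1 stood at 10.19 and Cd3g at 6.63, apart from the other arrays, while Epcam lay between 8.52 and 8.67 in all 4.

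The T and NK cell list fell by a mean of 0.88 in MMTV-Cre (SE over 13 members 0.20, camera adjusted p = 0.00110, unadjusted p = 0.335 with an estimated correlation). Its mean stood 1.32 above its average in wild-type replicate 1 and between −0.40 and −0.47 in the other 3 arrays. Without wild-type replicate 1 the mean difference was 0.01 and the direction turned (adjusted p = 0.776), and without MMTV-Cre replicate 2 the call ended (0.112). Of its members 12 had differences below 0, and 1, Cd5, was lower in both MMTV-Cre arrays, with a log2 difference of −0.91 (−1.68 to −0.14). None passed alone, also adjusted over the list alone. The B cell list had only 4 measured members and was not tested, with a mean of 1.20 above its average in wild-type replicate 1. The macrophage and dendritic cell list did not pass (mean −0.20, adjusted p = 0.161) and stood 0.32 above its average in the same array. It passed downward without MMTV-Cre replicate 2 (adjusted p = 0.00434) and without wild-type replicate 2 (0.000149), and turned upward without passing when wild-type replicate 1 was left out (mean 0.02, 0.947) or MMTV-Cre replicate 1 (0.580).

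Interferon-stimulated genes rose by a mean of 0.16 (SE over 22 members 0.05, camera adjusted p = 0.00637, unadjusted p = 0.377 with an estimated correlation). Of the members 18 had differences above 0, 6 were higher in both MMTV-Cre arrays and 0 passed alone, also adjusted over the list alone. The antiviral genes Oas2 and Oasl2 differed by 0.57 (0.25 to 0.89) and 0.33 (−0.11 to 0.76), Rtp4 by 0.51 and Parp14 by 0.31. The list's mean stood at −0.25 in wild-type replicate 1, the array with the lymphocyte transcripts, at 0.09 in wild-type replicate 2, and at −0.01 and 0.18 in MMTV-Cre. Without wild-type replicate 1 the mean difference was −0.00 (adjusted p = 0.929), and without MMTV-Cre replicate 2 the call ended (0.255).

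Fibroblast genes rose by a mean of 0.13 (SE over 21 members 0.05, camera adjusted p = 0.0252, unadjusted p = 0.455 with an estimated correlation). Of the members 17 had differences above 0, 6 were higher in both MMTV-Cre arrays and 0 passed alone, also adjusted over the list alone. The collagen genes Col1a1, Col3a1 and Col6a3 differed by 0.32, 0.47 and 0.34, and Dpt, a matrix protein gene, by 0.36. The list's mean stood at 0.30 in MMTV-Cre replicate 2 and at −0.16 in MMTV-Cre replicate 1, which lay below both wild-type arrays. The direction turned without MMTV-Cre replicate 2 (mean −0.10, adjusted p = 0.734) and the mean was 0.36 without MMTV-Cre replicate 1 (4.88e-07). The call ended without wild-type replicate 1 (mean 0.12, 0.189) and without wild-type replicate 2 (mean 0.15, 0.0558).

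**Figure D3:**
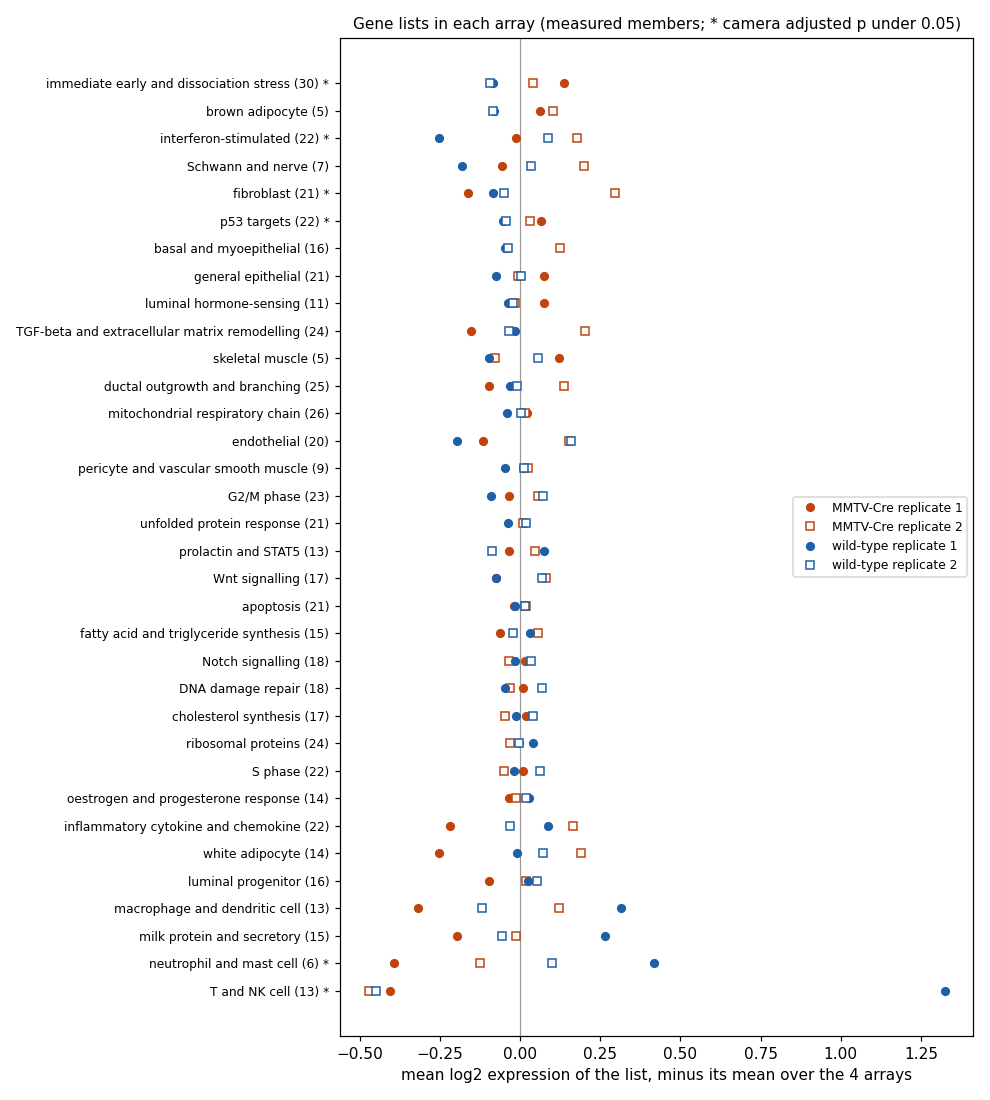
For each of the 34 tested lists, 1 point per array gives the mean log2 expression of the measured members (number in parentheses) minus its mean over the 4 arrays, and an asterisk marks camera adjusted p under 0.05 with the preset correlation. The T and NK cell list stood at 1.32 in wild-type replicate 1, and the immediate early list stood at 0.14 and 0.04 in MMTV-Cre and at −0.09 in both wild-type arrays.

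Single genes with the clearest separation did not pass the threshold. Means were at least 1.5-fold apart with separate groups in 99 genes, 36 higher and 63 lower in MMTV-Cre. Of the 63 lower genes, 11 were among those standing at least 1 log2 unit above every other array in wild-type replicate 1. The genes with an unadjusted p under 0.05 divided into 249 higher and 255 lower. Among the 24 genes taken by the rule for their separation, the largest difference was that of nonagouti (symbol a, Entrez Gene 50518), which encodes a signal for pigment type. It stood at 3.49 and 4.00 in MMTV-Cre and at 2.09 and 2.44 in wild-type, a log2 difference of 1.48 (0.91 to 2.05), with both wild-type values below the 2.84 set as the limit for dim genes, where the size of a difference is uncertain. Others higher in both MMTV-Cre arrays were the metalloproteinase inhibitor gene Timp4 by 0.69 (0.39 to 1.00), the ATP-gated channel gene P2rx7 by 0.64 (0.34 to 0.94), the mitotic kinase gene Aurka by 0.64 (0.33 to 0.94), Tspan6 by 0.64, and Eln, which encodes elastin, by 0.62 (0.31 to 0.92). The remaining higher genes were Rps27, Vmn1r157, Olfr311, Slc28a2, Mb21d2 and Kcne1l, with log2 differences from 0.61 to 0.97. Genes lower in both MMTV-Cre arrays besides Mcpt4 included C1qtnf4 with a log2 difference of −0.84 (−1.14 to −0.55), the proton pump subunit gene Atp6v1f with −0.77 (−1.07 to −0.47), the aldo-keto reductase gene Akr1b8 with −0.73 and the lipid droplet gene Plin5 with −0.62. Cyria, Traf1, Zfp53, Zfp942, Herc3, Ccdc62 and the epithelial transcription factor gene Grhl3 had differences between −0.60 and −0.81. Most of these levels lay near the dim end of the arrays, such as 2.85 and 3.70 for the group means of C1qtnf4.

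By limma 0 genes passed at an adjusted p under 0.05 (smallest 0.964), 504 had an unadjusted p under 0.05 where chance gives 583, and 3866 genes (33.1%) had separate groups where chance gives 33.3%. With 2 arrays per group the median half-width of a gene's 95% interval was 0.34 log2 units and the smallest two-sided exact permutation p is 0.333, so the precision for single genes is low.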

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

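All alternatives were planned before the data were examined. The count of genes past the threshold stayed at 0 in every alternative that kept all 4 arrays with an adjusted p, was 504 at an unadjusted p under 0.05 (1012 with no filter and 259 with the stricter one, from other numbers of genes tested), and ran from 0 to 13 without 1 array each, the 13 without wild-type replicate 2. Each such fit leaves a group with 1 array, assumed to vary like the other group. The number of lists passing was 6, 7 with no filter on dim probe sets (B cell and Schwann cell genes added at 0.0229 and 0.0444, p53 targets lost), 3 with the stricter filter on dim probe sets, under which the T and NK cell and the mast cell lists had too few members, 0 with an estimated correlation, 0 by fry, and 2 to 9 without 1 array each. The 2 were the immediate early and the mast cell lists, without wild-type replicate 1, and the 9 came without MMTV-Cre replicate 1. With an estimated correlation each of the 6 lists had an adjusted p of 0.955, which with so few arrays does not decide about the lists. By fry it was 0.642 for p53 targets, immediate early genes and mast cells and 0.963 for interferon, fibroblast and T and NK cell genes. The p53 list had 0.114 with no filter and 0.137 with the stricter one. Without 1 array each, adjusted p ran from 0.0283 to 0.298 for p53 targets, 4.23e-06 to 0.929 for interferon genes, 4.88e-07 to 0.734 for fibroblast genes, which turned downward without MMTV-Cre replicate 2, and 1.24e-22 to 0.776 for T and NK cells, which turned upward without wild-type replicate 1. These fits hold fewer samples, and beyond that the cause was not tested. The variance trend and robust variance do not enter camera and so test nothing about the lists. Of 180 named genes 20 changed sign in some alternative, and 0 of the 24 with the clearest separation did. With the replicate block 0 genes and 6 lists passed, and 445 genes had an unadjusted p under 0.05. The deviations of same-numbered arrays correlated at −0.039 across genes, which is 1 value for both pairs, and the labels do not say what a number marks, so no pairing was assumed. Signal over background limits the many genes near the dim end.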

Other observations

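The tests of epithelial share and genotype for the lymphocyte transcripts, and the 3 tests of the immediate early genes, were chosen after the result was seen. The genes of contraction and brown fat, the examples Cd52 and Ccr7 and the named neighbours of nonagouti were picked out after their values were seen.

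Among contractile genes of the myoepithelium, 4 were higher in both MMTV-Cre arrays than in both wild-type arrays, although none passed the limma threshold and their list did not either. The log2 difference was 0.40 for Acta2 (95% interval 0.06 to 0.75), 0.32 for Actg2, 0.31 for Cnn1 and 0.21 for Lmod1. Other contractile genes of the list overlapped between the groups, with 0.21 for Mylk, 0.19 for Myh11 and −0.01 for Tagln, and the list passed only in the fit without MMTV-Cre replicate 1 (adjusted p = 0.0236). The brown fat genes Dio2 and Ucp1 differed by 0.47 (0.07 to 0.87) and 0.33 (−0.00 to 0.65). Of the other 3 measured members Cox7a1 differed by 0.10, Cidea by −0.06 and Cox8b by −0.01. The brown adipocyte list did not pass camera (adjusted p = 0.169) and was the 1 list with an unadjusted p under 0.05 by limma's fry, with an adjusted p of 0.599.

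Lymphocyte transcripts were high in wild-type replicate 1 alone. A lower epithelial share with more of every other cell type would raise fibroblast, endothelial and white adipocyte markers. Their median excess in wild-type replicate 1 was −0.17 (55 genes), against 1.43 for 13 T and NK cell genes (SD 1.38), which argues against such a general shift. A share lowered by lymphocytes alone would not raise those markers, so the values do not test it. General epithelial genes had a median excess of −0.09 in that array. An effect of genotype would also show in wild-type replicate 2, whose T and NK cell genes lay 0.0144 above MMTV-Cre (SD 0.26) against 1.36 for wild-type replicate 1, which argues against that too. Lymph node carried over into this sample stays open as a candidate explanation, although the labels call the tissue lymph node-free. Further lymph node genes, listed before their values were looked at, had a median excess of 0.465, short of the 0.5 set beforehand. Their excesses ran from −0.24 for Ebf1 to 1.80 for Cd52. Of the 23 genes, 19 (82.6%) were highest there, such as Cd52 at 5.51 and Ccr7 at 5.90. Equal odds for each array would give 25%. That comparison is no test, since the array was singled out for its lymphocyte transcripts and the genes include those of T and B cells. Glycam1 is a gene of lymph node vessels and also of milk secretion. The milk genes Csn2, Lalba and Muc15 did not rise with Glycam1 in wild-type replicate 1. They stood there at 2.56, 3.59 and 5.02, against 2.65 to 3.70, 3.48 to 3.90 and 5.18 to 5.47 in the other arrays. The other T and B cell genes do not tell lymph node from lymphocytes within the gland.

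The immediate early list was higher in MMTV-Cre by camera with a preset correlation and not with an estimated one (adjusted p = 0.955), and 17 of its 30 members had separate groups. Dilution of wild-type replicate 1 by lymphocytes is argued against, since the mean difference was 0.181 (SE over members 0.03) against wild-type replicate 2 alone and 0.177 with all arrays. Handling of the tissue stays open. The 6 heat shock members differed by 0.176 between the groups but belong to the list, so this is no separate evidence. The limit asked heat shock and other members to differ together, by over 0.1 in one direction, between the 2 arrays of each group. It was not met, with 0.17 in MMTV-Cre and −0.08 in wild-type for heat shock and 0.08 and 0.03 for the other members. A p53 response to Cre also stays open: p53 targets outside the list differed by 0.0861, less than the list, but the gap of 0.09 had an interval over arrays of −0.07 to 0.25. The limits of these last tests were revised after a first result, under which the p53 mean plus 2 standard errors over members, 0.145, lay below the list's 0.177 and counted against p53, and were replaced because members are not replicates, while handling was left open by both limits.

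A stretch of passenger chromosome or an insertion beside the transgene could make neighbouring genes differ together. The largest mean absolute limma t over 20 neighbouring genes was 1.67, against a median of 1.69 for the largest after shuffling gene order (10000 shuffles, permutation p = 0.562). No segment of that length stood out, which does not exclude one in which few of the 20 genes differ. Shorter segments were not tested. Around nonagouti, picked for its difference, 20 neighbours had a mean absolute t of 1.30, reached by 3.18% of windows, with Pxmp4 and Trp53inp2 at 0.59 and 0.46 and Bpifb2 and Cbfa2t2 at −0.63 and −0.52.

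Of the 3 splits of the 4 arrays into 2 and 2, all 3 gave at least as many genes at an unadjusted p under 0.05 as the real one, with 504 for the real split and 625 for the highest other, and 3 splits are too few for a share under 0.05. Among 8324 probe sets outside the comparison, with several genes or none named here, 0 passed by limma at an adjusted p under 0.05 and 463 had an unadjusted p under 0.05.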
